A study of Drosophila melanogaster with 7 samples.

How the data were processed

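Wing imaginal discs of third-instar larvae were profiled in 7 libraries, 3 of the wild type (WT) and 4 of the ds38k genotype. Per the labels' protocols, RNA was extracted with a ReliaPrep kit, libraries were made from 10 ng of total RNA with 12 to 15 amplification cycles and unique dual indexes, and fragments were read from both ends over 150 bases on a NovaSeq 6000. Whether polyadenylated RNA was selected or ribosomal RNA removed, whether strand was kept, the dissection dates and the library batches are not given in the sources used here. The column names of the WT libraries carry a tag that those of ds38k lack, and its meaning is not given either.

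The deposited table holds estimated counts per gene and library, not scaled between libraries. Per the submitters' processing notes, FastQC 0.10, Trimmomatic 0.33, Salmon 1.80 (the version as written there) and edgeR were used, and the genome build was dm6; the annotation release is not given in the sources used here. Salmon divides reads that match several transcripts by a model, so the counts of near-identical genes (rRNA copies, Hsp70 copies, histone genes, Sdic genes) are uncertain, as are those of overlapping and antisense genes. PCR duplicates cannot be recognised in such counts, and intervals and floors cover counting error only.

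The expected counts were rounded to whole numbers. Of 17208 gene identifiers 17083 were found in the annotation used here (BDGP6.54, which has dm6 coordinates) and in the gene name table, 16098 of them under the same symbol; the symbols of the deposited table were kept. All columns were mapped to a sample by the names the labels give, and 0 were left over. Replicate libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 37.4 to 240 between libraries of 1 group, so each was counted as 1 sample.

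The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for figures. Genes were kept by edgeR's filterByExpr with the genotype as group (minimum count 10), which left 9294, and library sizes were scaled by TMM factors. The main test was edgeR's quasi-likelihood F-test of genotype without covariates over all 7 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are scaled by the TMM factors, except for the sums over lists and RNA classes, the shares of the counts and the genes present in some replicates only, which use the total count; log2 CPM used a prior count of 2. Standard errors of log2 fold changes were derived from the same fit, as the size of the log2 fold change divided by the square root of F. They are approximate, above all for genes without counts in a group. Single values per library were compared by exact two-sided permutation over the 35 splits of 7 libraries into 3 and 4, where the smallest possible p is 0.0286.

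The text names genes by a rule set before the data were examined: ds, ft, fj, d, ex, Diap1, yki and wts; the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups; up to 4 members with the smallest p of each gene list; and genes singled out in the closing section. All other names were chosen after their values were seen. The 35 gene lists were fixed at the same time from textbook knowledge, and cover the Fat/Dachsous, Hippo, planar polarity and other patterning pathways, growth, timing, metabolism and stress, and markers of tissues that can adhere to a dissected disc. A few members were not found in the table under the listed symbol (msh, scarface, let-7-C and tal; the gene msh is listed as Dr as well), and the cuticle pattern also takes in Cpr, the P450 reductase gene. Lists were tested with camera (inter-gene correlation 0.01, and estimated per list) and with fry, adjusted over the lists. With an estimated correlation no list passed camera. In the main fit fry passed many lists that camera with a correlation of 0.01 did not. These were 11 lists for movement in 1 direction and 18 for changes in either. A small fry value alone therefore does not single out a list. Folds against a group with no counts use a floor of 3 counts in each library.

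After the fold changes had been seen to fall with transcript length, a length correction was added. In each library the deviation of log2 CPM from the gene mean was fitted on the log2 of the median annotated transcript length by a natural spline with 5 degrees of freedom, and the fitted trend entered edgeR as an offset. This removes any real change that runs with transcript length as well. It left 9224 genes with a length, and zip, for one, has no length in the annotation used here. No genome sequence was used here, so GC content was not checked.

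The procedure was tested on simulated counts for 9117 genes in 3 and 4 libraries, some of them changed by known factors. It recovered 45% of 2-fold and 92% of 4-fold changes, and 0.725% of its calls were false. With a simulated length trend 2554 unchanged genes (28.7%) were called without the correction and 6 (0.0680%) with it, and 49% of 2-fold and 90.9% of 4-fold changes were recovered. The simulated trend was the one fitted to these libraries, which the correction is built to remove. The low count with the correction was therefore given by construction. It does not show that corrected calls in the real data are free of length bias.

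Alternatives set before the data were examined were size factors by the median of ratios, upper-quartile factors, DESeq2, limma-voom with sample quality weights, no low-count filter, a filter at 1 CPM in at least 3 samples, a test against a fold change of 1.2, an adjusted p under 0.01, the replicate number as a block on 6 samples, the same 6 samples without it, and each library left out in turn. Alternatives added after seeing the data were the length correction, leaving out the rRNA genes, ds38k replicate 4 as the only mutant library, and the length correction with ds38k replicate 4, with WT replicate 1 or with ds38k replicates 1 to 3 left out. The positions of called genes were compared between chromosome arms and around ds.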

Results

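Gene expression in wing imaginal discs of third-instar Drosophila melanogaster larvae was measured by RNA sequencing. The wing imaginal disc is the epithelial sac of the larva from which the adult wing and part of the thorax form. There were 7 libraries, 3 from wild-type (WT) discs of the w1118 stock and 4 from discs of ds38k mutants. The total count per library was 21438604 to 31718937 in WT and 25192527 to 31141974 in ds38k. The table held 17208 genes, of which 9294 had enough counts to be tested. Because the labels do not say that the replicates came from separate animals or dissections, each p-value measures only the spread between these samples, which may be technical.

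The comparison asked how transcription in the wing disc differs when ds is mutated, in a study of the planar polarity and Hippo signalling functions of the Fat and Dachsous cadherins. Transcripts of ds itself, which encodes the atypical cadherin that binds Fat, fell 7.74-fold in ds38k discs, or 2.28-fold with a correction for transcript length. The gene expanded (ex), which encodes an upstream regulator of the Hippo kinases, fell 7.52-fold, or 2.64-fold with that correction. It lies within 1 Mb of ds, at 2L:431227-448701. A difference linked to the mutated chromosome thus cannot be told apart from a response of the pathway. Of 28 reported target genes of Yorkie, the transcriptional co-activator that Hippo signalling restrains, 18 fell and 1 rose, but 6 fell and 5 rose with the correction. The gene ex is also one of these targets, so its fall has the opposite direction to a gain of Yorkie activity. Of 83 cytosolic ribosomal protein genes, 80 rose and 0 fell (78 and 0 corrected), and of 30 genes of the ecdysone response, the steroid programme that times metamorphosis, 14 rose and 9 fell (15 and 5 corrected). The libraries also differed in composition: short transcripts and ribosomal RNA (rRNA) took a larger share of the ds38k counts and long transcripts a smaller one, so the counts of each gene list are given with and without the correction.

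The ds gene (FBgn0284247; dm6 2L:640013-714983, minus strand) had 1547, 1422 and 1701 counts scaled to the library size (CPM) in WT replicates 1 to 3 and 229, 200.3, 215 and 161 CPM in ds38k replicates 1 to 4. Its mean was 1557 ± 139.98 CPM (SD, n = 3) in WT and 201 ± 29.2 CPM (SD, n = 4) in ds38k, a log2 fold change of -2.95 ± 0.14 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.7e-06). The lowest WT library lay above the highest ds38k library, and the exact two-sided permutation test of log2 CPM gave p = 0.0286, the smallest value that 35 splits of 3 and 4 libraries allow. With the length trend removed the log2 fold change was -1.19 ± 0.08 (edgeR adjusted p = 9.3e-05), so the size of the fall in ds depended on that correction while its direction did not.

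Across all tested genes, edgeR called 3183 higher and 2859 lower in ds38k at an adjusted p under 0.05, together 65.0% of the genes. At least 2-fold differences made up 1532 of the higher and 1820 of the lower calls. The CPM ranges of the groups did not overlap for 6167 genes, 66.4% of those tested, where chance gives 5.71%. Scaling mattered for the balance: with upper-quartile factors 3990 genes were higher and 2259 lower, 63.9% higher against 52.7% in the main analysis, and the median log2 fold change of all genes was 0.33 against 0.07. With the length trend removed, 2547 genes were higher and 1760 lower among 9224 tested. Calls made with and without the correction in the same direction covered 1971 genes for higher and 1482 for lower, and 239 genes were called in opposite directions.

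The composition of the libraries separated the groups without overlap. Annotated rRNA genes took 1.13% ± 0.336 (SD, n = 3) of the WT counts and 13.3% ± 1.56 (SD, n = 4) of the ds38k counts, and ribosomal protein genes took 2.53% ± 0.290 and 10.6% ± 0.581. Protein-coding genes with a median annotated transcript of at most 1000 bases held 5.18% ± 0.419 of the WT counts and 14.7% ± 0.799 of the ds38k counts. Those of at least 5000 bases held 18.0% ± 1.02 and 4.61% ± 0.281. Each of these differences had an exact two-sided permutation p of 0.0286, or 0.0714 after Benjamini-Hochberg adjustment over 15 measures, which misses 0.05. Most of the rRNA count in ds38k lay in the copy 28SrRNA:CR45837, with 102561 to 140337 CPM in ds38k and no counts in WT. Counts of such near-identical copies are uncertain, so the size of the rRNA gap is uncertain as well. Across 8598 protein-coding genes, which are not independent replicates, Spearman's rho between log2 fold change and transcript length was -0.60, and it was -0.14 after correction. The median log2 fold change ran from 1.10 to -1.60 over 10 equal classes of genes from the shortest (162 to 810 bases) to the longest. Between libraries of the same group the size of this rho was at most 0.32 in WT and 0.33 in ds38k, whereas it lay between -0.60 and -0.55 for each ds38k library over each WT library.

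**Figure D1:**
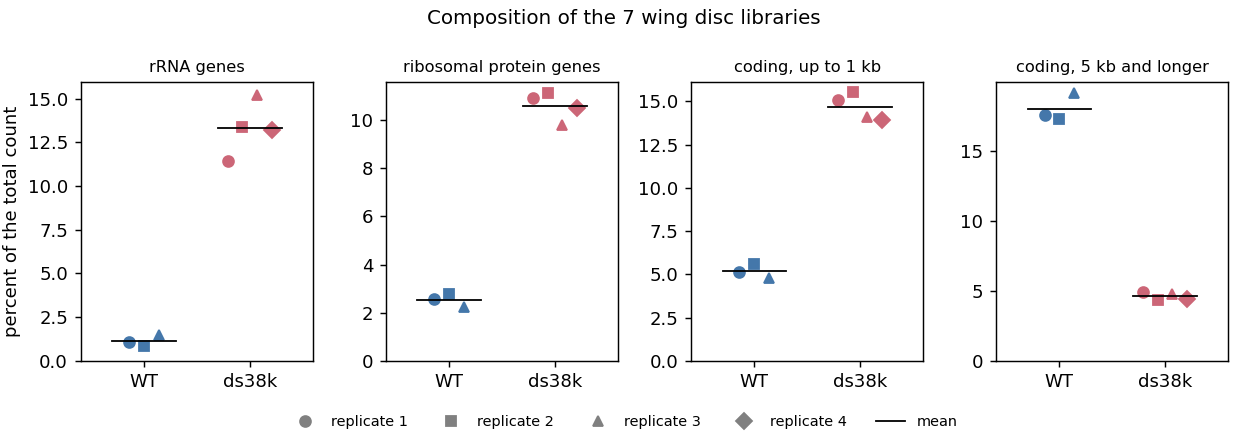
Percent of the total count of each library (y axis) taken by rRNA genes, ribosomal protein genes, protein-coding genes up to 1 kb and protein-coding genes of 5 kb and longer, with 1 point per library and a line at the group mean. The 4 ds38k libraries lie at 11.4% to 15.2% for rRNA genes, against a mean of 1.13% in WT. Most of that ds38k share is the copy 28SrRNA:CR45837, which has no counts in WT.

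**Figure D2:**
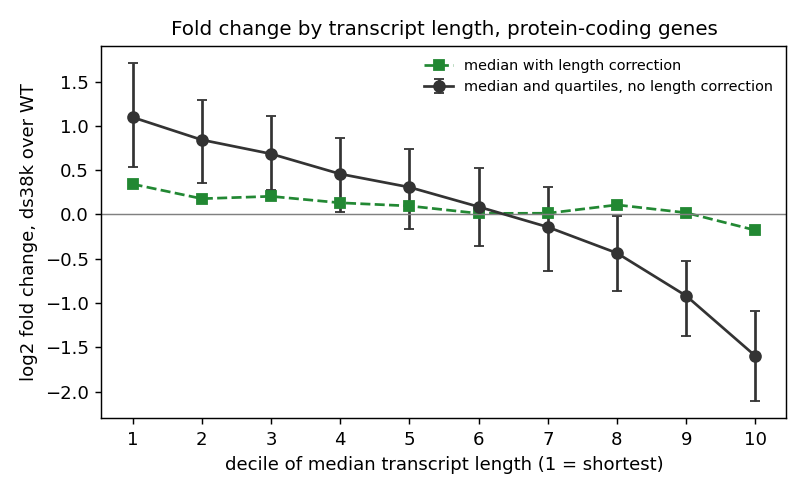
Median log2 fold change of ds38k over WT (y axis) in 10 equal classes of protein-coding genes ordered by annotated transcript length (x axis, 1 is the shortest), with bars from the lower to the upper quartile; green squares show medians after the length correction. The uncorrected median falls from 1.10 to -1.60 and the corrected one runs from 0.34 to -0.18.

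Of 34 Fat/Dachsous and Hippo pathway components, 22 fell and 4 rose, counts that were the same adjusted over the list alone. The genes mask, whose product is a cofactor of Yorkie (log2 fold change -2.51 ± 0.10, SE), crb, an apical polarity determinant (-1.89 ± 0.09), and kibra, a scaffold upstream of the Hippo kinase (-1.83 ± 0.13), fell in all 4 ds38k libraries. The kinase gene wts fell by 1.46 ± 0.11 and the unconventional myosin gene d by 1.65 ± 0.16 on the log2 scale. The ft gene, which encodes the Fat cadherin, fell by 1.23 ± 0.13 and fj, which encodes a kinase that phosphorylates cadherin domains of Fat and Dachsous, fell by 0.55 ± 0.14. The log2 fold change of yki was 0.28 ± 0.33 (edgeR adjusted p = 0.47). The 4 that rose, named after their values were seen, were Dlish, lft, mats and Mob4. The camera test placed the list below other genes (adjusted p = 6.2e-04), but with an estimated correlation the adjusted p was 0.369.

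These genes have long transcripts, and the length correction changed their picture: 10 of the 34 then fell and 6 rose, with a camera adjusted p of 0.102. Besides ds, the corrected falls included ex (-1.40 ± 0.20, edgeR adjusted p = 0.0014), mask (-0.73 ± 0.11) and kibra (-0.51 ± 0.13), while crb was no longer called (-0.27 ± 0.11, 0.072). The gene dco, which encodes a casein kinase that acts on Fat and was picked after its values were seen, fell by 3.93 without and by 3.33 with the correction. The corrected value of wts was -0.05 ± 0.08 (edgeR adjusted p = 0.68) and that of d was -0.38 ± 0.15 (0.069). The direction of ft turned, to 0.54 ± 0.17 (0.034), and fj had a corrected value of 0.23 ± 0.11 (0.14). Of the 4 rises those of mats (from 0.55 to 0.09 ± 0.08, edgeR adjusted p = 0.361) and Mob4 (from 0.43 to 0.07 ± 0.08, 0.499) were no longer called.

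**Figure D3:**
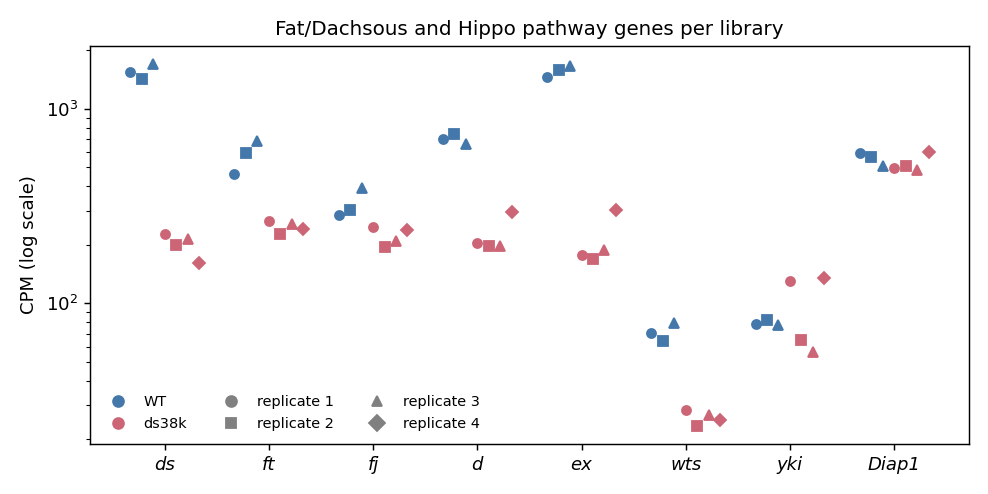
CPM on a log scale (y axis) of 8 Fat/Dachsous and Hippo pathway genes (x axis) in each library, with WT in blue, ds38k in red and the replicate number as the marker. The ds points fall from 1422 to 1701 CPM in WT to 161 to 229 CPM in ds38k, while the ranges of yki and Diap1 overlap between the groups.

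Among the 28 reported Yorkie targets the 18 that fell included ex, crb and kibra, the glypican gene dally (-1.72 ± 0.12) and Ser, which encodes a ligand of Notch (-1.57 ± 0.12). The count was the same adjusted over the list alone. Diap1, which encodes an inhibitor of apoptosis, had a log2 fold change of -0.09 ± 0.10 (edgeR adjusted p = 0.49). The single member that rose was Rae1, named after its value was seen. The list lay below other genes by camera (adjusted p = 0.0010), with an adjusted p of 0.587 with an estimated correlation. After length correction 6 members fell, 5 rose and the camera adjusted p was 0.235; dally still fell (-0.77 ± 0.09), and Ser had a value of -0.19 ± 0.14 (edgeR adjusted p = 0.29).

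In the list of 21 planar cell polarity genes 15 fell and 3 rose, also when adjusted over the list alone. The dsh gene (X:11355881-11358724), whose product transduces Frizzled signals in the polarity and Wingless pathways, fell from 95.7 ± 11.3 CPM (SD, n = 3) to 4.80 ± 1.07 CPM (SD, n = 4), a log2 fold change of -4.32 ± 0.20 (SE; edgeR adjusted p = 4.8e-06). That fall was -3.93 ± 0.22 with the length correction. Of the myosin II genes zip, which encodes the heavy chain, fell by 1.11 ± 0.09, and sqh, which encodes the regulatory light chain, rose by 1.31 ± 0.07, or 0.73 ± 0.07 with the correction. Since zip has no length in the annotation, its fall cannot be checked against the length trend, nor can this contrast. The other members that rose, picked after their values were seen, were fy and nmo. The camera adjusted p was 0.0167, and 0.411 with an estimated correlation. After length correction 9 of 20 members rose and 3 fell, and the camera direction was upward with an adjusted p of 0.810. Of 14 cadherin family genes 12 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 3.6e-05, and 0.369 with an estimated correlation). Cad74A fell by 2.26 ± 0.09 and shg, which encodes E-cadherin, by 1.61 ± 0.08, values that were -0.75 ± 0.11 and -0.12 ± 0.10 with the correction, where shg was not called (edgeR adjusted p = 0.349). After length correction 4 fell and 2 rose (camera adjusted p = 0.613, downward although the median was 0.11).

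In the pouch, hinge, Hedgehog and Dpp, and Wingless lists more genes fell than rose before length correction. Of 13 pouch genes 12 fell, the same adjusted over the list alone, among them salm, a target of Dpp signalling (-2.91 ± 0.37), and nub, a transcription factor of the wing field (-1.27 ± 0.21). The camera adjusted p was 0.0032, and 0.608 with an estimated correlation. With the length correction 4 fell and 1 rose (0.124); salm was at -1.46 ± 0.33 and nub at -0.65 ± 0.18, and salr turned from -0.60 to 0.50. Of 15 hinge genes 7 fell and 1 rose, with falls of zfh2 (-2.78 ± 0.20) and tio (-2.50 ± 0.10) that were -1.03 and -1.11 after length correction. The hinge list had a camera adjusted p of 0.0326, and 0.587 with an estimated correlation; without WT replicate 3 it was 0.0529, and with the length correction it was 0.1002, with 4 falls and 1 rise. Of 26 Hedgehog and Dpp pathway genes 17 fell and 1 rose (camera adjusted p = 4.2e-04, and 0.587 with an estimated correlation). The crossveinless gene cv, which modulates BMP signalling, fell by 3.10 ± 0.10, and by 3.32 ± 0.10 with the length correction. In that fit the list had 8 falls and 5 rises (camera adjusted p = 0.127). Of 25 Wingless pathway genes 13 fell and 5 rose, or 14 and 5 adjusted over the list alone (camera adjusted p = 0.0281, and 0.587 with an estimated correlation). Apc, part of the complex that destroys beta-catenin, fell by 2.10 ± 0.09, or 0.43 ± 0.07 with the correction; the corrected counts were 5 falls and 7 rises (0.810). For the hinge and the Hedgehog and Dpp lists the counts adjusted over the list alone were the same.

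Of 24 measured genes of the Notch list 11 rose and 7 fell, the same adjusted over the list alone. The 11 that rose were genes of the E(spl) complex, which Notch signalling activates, a grouping seen only in the values and not tested. E(spl)m3-HLH rose by 1.77 ± 0.10, E(spl)malpha-BFM by 2.09 ± 0.19 and E(spl)m2-BFM by 1.67 ± 0.14 on the log2 scale. The 7 that fell included Ser and, picked after their values were seen, N, mam and H. Camera gave an adjusted p of 0.665. With the length correction 15 rose and 4 fell, with a camera adjusted p of 0.0408, and 0.582 with an estimated correlation; E(spl)m3-HLH was then at 1.34 ± 0.10, and N turned from -1.11 to 0.62 ± 0.11 (edgeR adjusted p = 0.0035). The E(spl) genes are short, like the ribosomal protein genes. Of 14 notum genes 4 rose and 3 fell, the same adjusted over the list alone, with sc, a proneural gene, up by 1.89 ± 0.14 and mirr down (-1.69 ± 0.14); camera gave an adjusted p of 0.798, and 6 rose and 1 fell after length correction.

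Ribosomal protein genes made the most uniform group, with 80 of 83 higher, the same adjusted over the list alone, and a median log2 fold change of 2.44. RpL36 rose from 90.5 ± 3.92 CPM (SD, n = 3) to 964 ± 42.2 CPM (SD, n = 4), or 3.41 ± 0.08 on the log2 scale (SE; edgeR adjusted p = 2.0e-06). RpS21 rose by 3.37 ± 0.10 and RpL32 by 3.35 ± 0.11. The 3 that were not called, named after their values were seen, were RpS10b, RpL23A and RpL22. By camera the adjusted p was 2.5e-37, and 0.369 with an estimated correlation. After length correction 78 rose and 0 fell with a median of 1.78, and RpL36 was at 2.66 ± 0.13. Of 23 ribosome biogenesis genes 12 rose and 6 fell, the same adjusted over the list alone, with nop5, a nucleolar protein gene, up by 1.43 ± 0.09 (camera adjusted p = 0.236). With the correction 13 rose and 1 fell (0.0284, and 0.582 with an estimated correlation). Of 70 oxidative phosphorylation genes 61 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 1.3e-13, and 0.512 with an estimated correlation), and ATPsynG rose by 2.10 ± 0.13. Their corrected counts were 41 rises and 1 fall, with a camera adjusted p of 7.2e-05, and 0.841 with an estimated correlation.

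The ecdysone list held large changes in both directions, with 14 of 30 members higher and 9 lower, the same adjusted over the list alone. ImpE2, an ecdysone-inducible gene of imaginal discs, rose from 473 ± 84.7 CPM (SD, n = 3) to 6694 ± 973 CPM (SD, n = 4), or 3.82 ± 0.19 on the log2 scale (SE; edgeR adjusted p = 5.6e-06), and by 3.58 ± 0.20 with the length correction. Eip74EF fell by 2.48 ± 0.18 and EcR, the ecdysone receptor gene, by 1.95 ± 0.17; corrected values were -1.03 ± 0.19 and -0.70 ± 0.13. The gene chinmo, which encodes a transcription factor of early larval identity, fell from 247 ± 50.3 to 14.1 ± 8.41 CPM (log2 fold change -4.13 ± 0.43, edgeR adjusted p = 1.4e-04; -2.69 with the correction). Among members picked after their values were seen, Hr3 (5.23 ± 0.86), Blimp-1 (3.81 ± 0.59), Hr4 (3.20 ± 0.49) and Eip78C (3.04 ± 0.36) rose, and ftz-f1, a nuclear receptor gene of the prepupal period, fell from 70.7 to 2.02 CPM (-5.11 ± 0.80). Without ds38k replicate 4 the value of ftz-f1 was -6.44, and without WT replicate 3 those of Blimp-1 and Hr4 were 4.54 and 3.91. With the length correction 15 members rose and 5 fell, and the median was 0.61 against 0.91 without it. Camera gave an adjusted p of 0.424, and 0.0284 with the length correction, where the estimated correlation gave 0.582. For changes in either direction fry gave the ecdysone list an adjusted p of 2.2e-05. That value was not specific to it, since fry gave 2.4e-05 for the notum and 2.5e-05 for the tracheal list. Not every list passed fry in this way, with 0.184 for the salivary gland list.

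**Figure D4:**
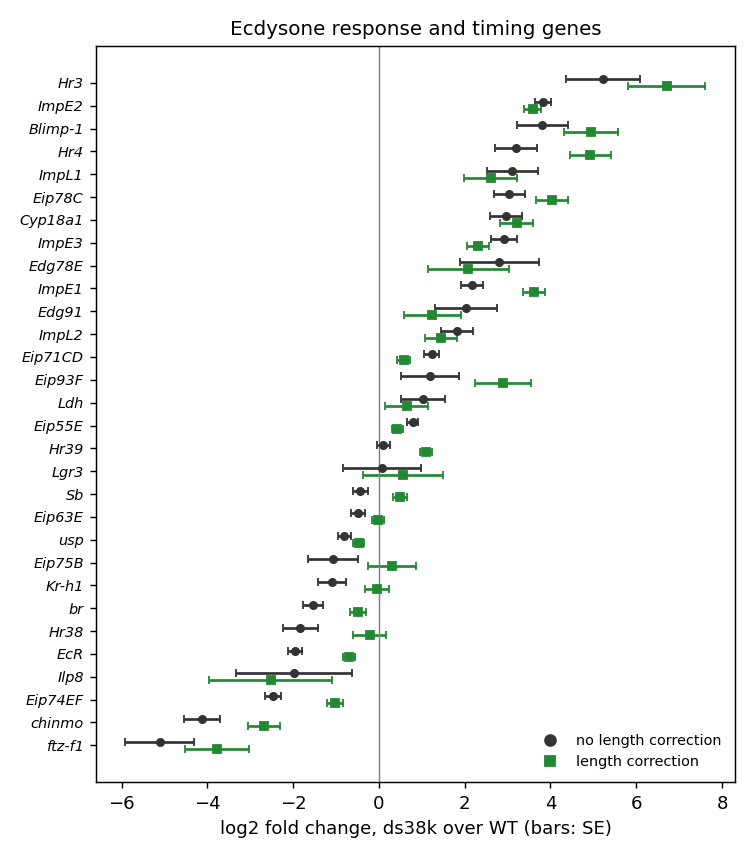
Log2 fold change of ds38k over WT with its SE (x axis) of 30 ecdysone response and developmental timing genes (y axis), without (black circles) and with (green squares) the length correction. ImpE2 lies at 3.82 and 3.58, and chinmo at -4.13 and -2.69.

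Cell cycle and cytoskeletal genes moved both ways. Of 40 cell cycle and DNA replication genes 10 rose and 18 fell, or 10 and 19 adjusted over the list alone, with geminin, an inhibitor of replication licensing, up by 1.66 ± 0.12 and BubR1, a spindle checkpoint gene, down (-1.29 ± 0.14). By camera the adjusted p was 0.523, and 12 rose and 6 fell with the length correction, where BubR1 was at -0.14 and not called. Of 36 cytoskeleton genes 11 rose and 19 fell, or 12 and 20 adjusted over the list alone. The spectrin genes beta-Spec (-2.02 ± 0.07) and kst (-2.67 ± 0.11) were among the falls, and the corrected values were -0.41 and -0.91. The camera adjusted p was 0.0437, and 0.512 with an estimated correlation. It lay above 0.05 with limma-voom (0.0652), without WT replicate 3 (0.0529), without ds38k replicate 1 (0.0625) and without ds38k replicate 2 (0.0612), and after length correction 13 rose and 4 fell (0.613, upward).

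Transcripts of other larval tissues were present at unequal levels. The summed CPM of the fat-body list was 136, 49.2 and 61.4 in WT and 953, 3086, 910 and 82.8 in ds38k replicates 1 to 4. For the salivary gland list it was 13.2, 0.252 and 0.149 in WT and 1353, 105, 26.5 and 0.353 in ds38k, and for the gut list 103, 109 and 114 in WT and 286, 89.3, 1065 and 115 in ds38k. Only pros and esg of the gut list passed the count filter, so its WT sums rest mainly on them and do not show gut RNA. The protease member Jon65Aiii had at most 0.149 CPM in WT and 63.7, 0.357, 328 and 0.0642 CPM in ds38k replicates 1 to 4. Of 10 measured fat-body genes 7 rose, among them Fbp1 (7.15 ± 1.495, or 7.94 without WT replicate 1 and 6.2 without ds38k replicate 2), a receptor gene for storage proteins. Adjusted over the list alone 7 rose and 1 fell, and with the length correction 7 rose and 0 fell. Of 7 glue protein genes of the salivary gland 4 rose, or 5 adjusted over the list alone, but 2 with the length correction, where CG7587 (log2 fold change 7.73 ± 2.92 against 8.55 ± 2.99, edgeR adjusted p = 0.0635) and Eig71Ee (6.83 ± 2.60 against 7.16 ± 2.64, 0.0655) were no longer called. In this list ds38k replicate 1 had the highest values: Sgs7 had 285, 18.8, 7.93 and 0.0366 CPM in ds38k and an edgeR adjusted p of 0.0285, which was 0.0680 without that library and 0.0802, 0.0980 and 0.0980 without WT replicates 1, 2 and 3. Without WT replicates 1, 2 and 3 the calls of Sgs8 (0.0737, 0.0856, 0.0856), CG7587 (0.104, 0.118, 0.118) and Eig71Ee (0.0690, 0.133, 0.136) were lost as well, that of Eig71Ee also without ds38k replicate 1 (0.131) or 2 (0.0581). The log2 fold changes were 12.85 for CG7587 and 10.58 for Eig71Ee without WT replicate 1. For Eig71Ee the value was 4.15 without ds38k replicate 1. Of 18 sarcomere genes 12 rose and 1, Msp300, fell, or 14 and 1 adjusted over the list alone, with TpnC73F at 67.2, 66.0, 144 and 7.79 CPM in ds38k against at most 1.28 CPM in WT. The summed CPM of the sarcomere list, in which Msp300 had the highest values, went the other way, from 3689 ± 961 (SD, n = 3) in WT to 1902 ± 561 (SD, n = 4) in ds38k (exact two-sided permutation p = 0.0286, and 0.0714 adjusted). Neither the fat-body (camera adjusted p = 0.161), the salivary gland (0.344) nor the sarcomere list (0.0657) passed. Camera gave 0.0125 for the fat-body and 0.0081 for the sarcomere list without ds38k replicate 4, 0.0173 for the sarcomere list with no low-count filter, and 0.0015 for the sarcomere list after length correction, where 14 rose and 0 fell (0.841 with an estimated correlation). Both measured genes of the gut list, pros and esg, were uncalled, also adjusted over the list alone (camera adjusted p = 0.798). With the length correction pros was called higher (log2 fold change 3.22 ± 1.05 against 1.44 ± 0.95, edgeR adjusted p = 0.0400). The gene esg, with no annotated length, did not enter that fit.

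**Figure D5:**
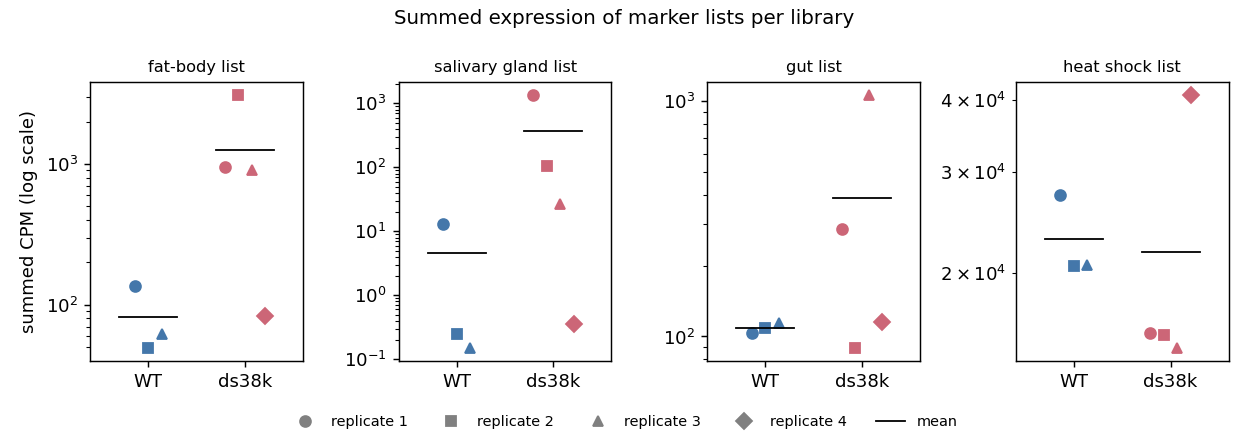
Summed CPM on a log scale (y axis) of the fat-body, salivary gland, gut and heat shock lists in each library, with 1 point per library and a line at the group mean. In ds38k replicate 4 the fat-body sum is 82.8 CPM, within the WT range of 49.2 to 136 CPM, and the heat shock sum is 40778 CPM, above all other libraries. The gut sums in WT rest mainly on pros and esg and do not show gut RNA.

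ds38k replicate 4 stood apart from the other 3 mutant libraries. Its log2 CPM values correlated with theirs across genes at 0.922 to 0.933, where those 3 correlated among themselves at 0.979 to 0.981, and all correlations between groups lay from 0.823 to 0.895. With ds38k replicate 4 as the only mutant library against the 3 WT libraries, 1979 genes were higher and 2042 lower, and 1206 and 868 with the length correction, where ds was at -1.35 (edgeR adjusted p = 0.0092). In that comparison 81 ribosomal protein genes were higher after length correction and 0 lower. The single mutant library is assumed there to vary like the WT libraries. Of 18 heat shock and chaperone genes 11 rose and 0 fell, the same adjusted over the list alone. Hsp27, a small heat shock protein gene, rose by 2.56 ± 0.13, and Hsp26 had 589, 543, 606 and 3322 CPM in ds38k against 33.4 to 41.5 CPM in WT. The camera adjusted p was 0.0296, and 0.738 with an estimated correlation, and it was 0.0550 with upper-quartile factors and 0.0554 with limma-voom. After length correction 13 rose and 0 fell (0.0050, and 0.841 with an estimated correlation). The member Hsc70-4, picked after its values were seen, had 10781 to 15773 CPM in WT and 247, 151, 125 and 7428 CPM in ds38k replicates 1 to 4. The summed CPM of the list, of which Hsc70-4 took a large part in WT, did not follow the counts of rises and falls. The sum was 15760, 15634 and 14846 in ds38k replicates 1 to 3, below every WT library (20596 to 27392), and 40778 in ds38k replicate 4. The group means were 22901 ± 3890 (SD, n = 3) in WT and 21755 ± 12689 (SD, n = 4) in ds38k (exact two-sided permutation p = 1).

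Several of the largest differences lay in repeated or overlapping genes, where reads can be shared between copies, or in antisense genes, for which the use of strand in the counting is not stated; their values are uncertain. The 28S rRNA copy 28SrRNA:CR45837 had no counts in WT and 102561 to 140337 CPM in ds38k, whereas pre-rRNA:CR45846 had 413 to 1363 CPM in WT and 0 to 1.31 CPM in ds38k. Further rises were those of 28SrRNA-Psi:CR45862, Hsp22 and Hsp70Bb, whose edgeR adjusted p of 0.0293 was 0.102, 0.0981 and 0.0982 without WT replicates 1, 2 and 3, and further falls those of Sdic2, CR32011, asRNA:CR46256 and asRNA:CR46029. Where a group had no counts, folds are lower bounds against a floor of 3 counts per library. On that basis lncRNA:CR45197 was at least 291-fold higher in ds38k, with 27.9 to 34.2 CPM, Pif1B at least 115-fold, CG7342 at least 23.8-fold (15.4-fold without ds38k replicate 2) and CG9686 at least 19.8-fold. The ppk13 gene (2L:21086790-21088751), which encodes an ion channel subunit, was at least 545-fold lower in ds38k, with 55.1 to 73.1 CPM in WT. Its neighbour CG33509 (2L:21084605-21086506) had 19.4 to 26.0 CPM in WT and a count in only 1 ds38k library, at 0.0374 CPM. CG32857 was at least 269-fold lower and lncRNA:CR46028 at least 27.6-fold lower, a bound that rested on WT replicate 1 (6.595-fold without it). Syt4 (64.2, 81.8, 82.8 and 1.17 CPM in ds38k) and CG42586 rose, and lncRNA:CR44978 fell.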

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

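The tests of transcript length for the number of calls and for the ecdysone genes, of other tissues for the ecdysone genes and of WT RNA in ds38k replicate 4 were chosen only after the results were seen, as was the rule behind the 71 genes described last.

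In the ds38k group of 4, a library was singled out where its gap to the nearest other library exceeded 0.829 of the group's range, which chance gives in about 5% of groups. ds38k replicate 4 was the highest by this measure for d (0.930), ex (0.858), Hsp70Bb (0.991), Hsp22 (0.956), Hsp26 (0.977), salm (0.906), tio (0.906), Col4a1 (0.832), eya (0.832), dsx (0.853), w (0.938) and f (0.896), and for the summed heat shock list (0.965). ds38k replicate 1 was the highest for Sgs8 (0.925), Sgs7 (0.934), CG7587 (0.960), Eig71Ee (0.911) and the summed salivary gland list (0.923), and for CG33509 (1, the only library with a count). ds38k replicate 2 was the only one with a count for asRNA:CR46256 (1), and ds38k replicate 3 was the highest for zip (0.839) and ci (0.867). The gene f, which was not called (adjusted p = 0.571), fell without ds38k replicate 4 (log2 fold change -1.49, edgeR adjusted p = 0.0169). Of the 154 named genes checked, 20 were singled out in this way. Over all tested genes 1006 (10.8%) were, with ds38k replicate 4 the highest library in 587 and the lowest in 181.

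Most tested genes differed between the ds38k and WT libraries: 6042 were called in the real split, and only that 1 of the 35 splits of the 7 libraries gave as many. The highest other split, which parted ds38k replicates 1 to 3 from the rest and points to a structure within the samples, gave 2065. A chance division of these libraries is thus argued against. The 35 splits allow no permutation p below 0.0286, however, and cannot tell genotype from batch. As the whole cause, a trend with median annotated transcript length is argued against by the 46.7% of tested genes called after its removal. Spearman's rho with length was still -0.14 after that removal, however. How many of these calls are free of length bias therefore cannot be told. RNA of other tissues in ds38k replicates 1 to 3 stays open: ds38k replicate 4 also lay beyond the WT range for 96.6% of called genes (5834), but the calls included that library, and 16 of 23 called fat-body, salivary gland and sarcomere genes (69.6%) likewise had it above all WT libraries. A difference in the selection of polyadenylated RNA stays open, because the RNA classes examined for it did not move together. The 13 histone genes, whose transcripts lack a poly(A) tail, had a median corrected log2 fold change of -0.088 but quartiles of -1.97 and 1.795. The rRNA share and the summed small nuclear RNA (2.44 CPM in WT and 142 CPM in ds38k) were higher in ds38k. Only 1 small nuclear RNA gene was tested, however. The summed small nucleolar RNA averaged 24.7 CPM in WT and 25.3 CPM in ds38k (exact two-sided permutation p = 0.857). A difference in library preparation or RNA quality that follows the genotype cannot be told apart from an effect of ds38k itself. The labels give no batch, while the WT column names carry a tag, of a meaning not given, that the ds38k names lack. Nor can a difference in genetic background between the w1118 stock and the ds38k mutants be told apart from an effect of ds38k. The genotype stays untested as the cause.

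Ecdysone response genes were higher in ds38k for 14 members of the list. As the whole cause, the length trend is argued against, since 50% of the whole list (15 of 30) was called higher after its removal, against 27.5% of other tested genes (Fisher's exact p = 0.0121) and 46.7% of the list before, with 12 members called both times. Fisher's test treats genes of the same libraries as independent, which they are not. After the length correction camera gave the list an adjusted p of 0.0284, or 0.582 with an estimated correlation. RNA of other tissues in ds38k replicates 1 to 3 stays open, since ds38k replicate 4 lay above the highest WT library for 100% of the 14 but also for 69.6% of 23 called fat-body, salivary gland and sarcomere genes. A difference in the age of the larvae at dissection may account for part of the pattern, as may the genotype; the labels give no age within the third instar, and neither was tested. Library preparation and genetic background stay open as well.

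A set of 71 genes reached about the WT level or more in ds38k replicate 4 only: at least 4-fold below the lowest WT library in the other 3 ds38k libraries and at least 0.5 of it in replicate 4, with a WT mean of at least 20 CPM. The same rule gave 0 genes for each of the other ds38k libraries, and examples picked after their values were seen are Hsc70-4 (247, 151, 125 and 7428 CPM in ds38k replicates 1 to 4 against 10781 to 15773 in WT) and RpL22 (173, 188, 183 and 2080 CPM against 881 to 1001). WT RNA in ds38k replicate 4 is argued against, since only 22.6% of the 314 genes at least 4-fold below the lowest WT library in replicates 1 to 3 reached that level there and 160 were at least 4-fold below it, and variants linked to 1 chromosome region are argued against by the 28.2% of the set on the arm with most of them, 3R, which holds 24.1% of tested genes. A length trend was not decided, as 62.9% of the 70 members with a length met the rule on corrected values. No biological explanation was tested, because the labels name no difference between the mutant replicates.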

How the results depend on the processing

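The length correction, leaving out rRNA genes and the comparisons with ds38k replicate 4 alone were chosen only after the data had been seen. The direction and call of ds held in every alternative, with log2 fold changes from -3.02 to -2.68 under the alternatives set beforehand (largest edgeR, DESeq2 or limma adjusted p 6.3e-05) and from -3.29 to -1.15 under the added ones (0.0092). Of the values of named genes under all alternatives, 3213 kept their direction and side of the threshold, 200 lost their call, 28 gained one and 44 turned direction; of the list tests the numbers were 720, 51, 57 and 6, and of the list counts 1271 stayed within 1.5 times and 339 did not. Leaving out each library in turn gave 2730 to 3341 higher and 2492 to 3190 lower genes. Other settings gave 3046 and 2993 (median of ratios), 3990 and 2259 (upper-quartile factors), 3191 and 3101 (DESeq2), 3501 and 3428 (limma-voom), 3064 and 2829 (no filter), 3019 and 2744 (1 CPM filter), 2773 and 2541 (fold change of 1.2) and 2402 and 2202 (adjusted p under 0.01). Camera was not run for DESeq2 or the test against a fold change of 1.2. Depth limits calls near the floor of 3 counts, which is 0.0856 to 0.128 CPM.

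No pairing is stated in the labels: correlations of deviations between libraries of the same number were 0.142, 0.043 and 0.130, although each library correlated best with its own number, a hint from the data and not from the design. With the replicate block on 6 samples 3364 genes were higher and 3180 lower, against 3341 and 3190 in the same 6 samples without the block. The count of lower ribosomal protein genes, 0 over all 7 libraries, was 1 with the block and without it in these 6 samples, which leave out ds38k replicate 4 (0 to 1 over all libraries left out), and also 1 with limma-voom and with ds38k replicate 4 left out and length corrected. Set against the same 6 samples, the block took the camera adjusted p of the salivary gland list from 0.282 to 1.3e-08 and that of the EGFR and FGF list from 0.0692 to 0.0456. Among named genes it moved the edgeR adjusted p of the log2 fold change of f from 0.0169 to 0.0565, and it changed no other call of a named gene or camera test.

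Counts of called genes moved by over 1.5 times in these cases, and the cause was not tested beyond the construction of each setting: lower genes with the length correction (1760), that correction with ds38k replicate 4 alone (868) and with WT replicate 1 left out (1552), and higher genes with ds38k replicate 4 alone (1979) and with the correction as well (1206), where a single mutant library is left. Yorkie targets higher were 2 with upper-quartile factors, 5 with the length correction, 2 with ds38k replicate 4 alone, 2 with that and the correction, 5 with the correction and ds38k replicate 4 left out and 4 with it and WT replicate 1 left out. Yorkie targets lower were 6 with the length correction, 8 with ds38k replicate 4 alone, 3 with both and 5 with the correction and WT replicate 1 left out. Their camera adjusted p was 0.235 with the length correction, 0.739 with ds38k replicate 4 alone as well, 0.0594 with ds38k replicate 4 left out, 0.260 with WT replicate 1 left out and 0.587 with an estimated correlation, which gave 0.369 for the ribosomal protein genes. Ecdysone genes lower were 5 with the length correction, 3 with ds38k replicate 4 alone as well and 4 with WT replicate 1 left out. Their camera adjusted p was 0.0284 with the length correction, 0.0127 with ds38k replicate 4 alone as well and 0.0302 with WT replicate 1 left out, and fry gave 0.0092 for movement in 1 direction and 2.2e-05 for changes in either.

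These results turned direction, and the cause was not tested beyond the removal of the length trend. With the length correction the log2 fold changes were 0.54 for ft, 0.23 for fj, 0.50 for salr, 0.017 for cos, 0.00074 for RpI1, 0.55 for Ppn, 0.064 for Col4a1, 0.42 for rols, 0.14 for Msp300 and 0.20 for Gli. With ds38k replicate 4 alone they were -2.33 for Sgs7 and -5.73 for Eig71Ee. With that and the length correction they were 0.83 for ft, 0.20 for fj, 0.45 for salr, 0.13 for vkg, 0.18 for Ppn, 0.50 for Col4a1, 0.29 for rols, 0.85 for Msp300, 0.18 for Gli, -2.47 for Sgs7, -5.77 for Eig71Ee and 0.00096 for Antp. With the correction and ds38k replicate 4 left out they were 0.43 for ft, 0.23 for fj, 0.50 for salr, 0.045 for cos, 0.023 for RpI1, 0.64 for Ppn, 0.45 for rols, 0.074 for kon, 0.038 for trh and 0.20 for Gli. With the correction and WT replicate 1 left out they were 0.39 for ft, 0.16 for fj, 0.54 for salr, 0.019 for RpI1, 0.57 for Ppn, 0.22 for Col4a1, 0.49 for rols, 0.11 for trh, 0.19 for Msp300 and 0.15 for Gli. The camera direction turned for the planar polarity list with the length correction (adjusted p = 0.810) and with WT replicate 1 left out as well (0.800), and for the cytoskeleton list with the correction (0.613), with ds38k replicate 4 alone (0.957), with it left out (0.606) and with WT replicate 1 left out (0.741).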

Other observations

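The search for genes present in part of a group and every use of the length correction were chosen only after the data had been seen. Among the glycolysis and the detoxification genes more rose than fell in ds38k, although neither list passed camera in the main analysis. Of 16 glycolysis genes 9 rose and 0 fell, the same adjusted over the list alone, with Tpi, the triose phosphate isomerase gene, up by 1.76 ± 0.23 and Eno, the enolase gene, by 0.92 ± 0.18 on the log2 scale (SE; edgeR adjusted p = 4.5e-04 and 0.0028). Camera gave the glycolysis and lactate list an adjusted p of 0.0677. Among the alternatives it ran from 0.0051 to 0.251, with passes under limma-voom (0.0194), with no low-count filter (0.0319), without WT replicate 1 (0.0109) and with that library left out and length corrected (0.0051), and it was 0.738 with an estimated correlation. With the length correction 6 rose and 0 fell. Of 60 detoxification genes 21 rose and 8 fell, or 19 and 7 adjusted over the list alone (camera adjusted p = 0.329). The superoxide dismutase gene Sod1 rose by 2.21 ± 0.19 and the catalase gene Cat by 1.22 ± 0.11, while the cytochrome P450 gene Cyp4ac2 on 2L fell by 5.12 ± 0.50. Its neighbours Cyp4ac1 and Cyp4ac3, picked after their values were seen, fell by 2.75 ± 0.34 and 4.34 ± 0.65. Corrected for length 16 detoxification genes rose and 5 fell.

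Signalling lists not yet described moved in both directions. Of 17 EGFR and FGF genes 2 rose and 8 fell, the same adjusted over the list alone, with ths, which encodes an FGF ligand, at -2.19 ± 0.15 and Egfr at -1.998 ± 0.21 (camera adjusted p = 0.120). With the length correction 6 rose and 2 fell, ths was at -0.88 ± 0.11, and Egfr was no longer called (-0.57 ± 0.22, edgeR adjusted p = 0.0730). Of 32 genes of JNK signalling, apoptosis and wound response 8 rose and 8 fell, or 8 and 7 adjusted over the list alone, with the initiator caspase gene Dronc at 0.83 ± 0.08 and Stat92E at -1.08 ± 0.09 (camera adjusted p = 0.523). With the correction 7 rose and 4 fell, Dronc was at 0.71 ± 0.08, and Stat92E was no longer called (-0.17 ± 0.07, edgeR adjusted p = 0.0911). Of 68 cuticle and chitin genes 24 rose and 18 fell, the same adjusted over the list alone, with kkv, the chitin synthase gene, at -1.65 ± 0.09 and Cda5 at -3.04 ± 0.28. The cuticle list had a camera adjusted p of 0.986 with a downward sign, whereas its median (0.12) and mean (0.79) were positive; 20 rose and 15 fell with the correction, where kkv was at -0.28 ± 0.08 and Cda5 at -1.56 ± 0.24.

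Markers of other cell types and discs gave few uniform shifts. Of 17 haemocyte markers 3 rose and 5 fell, or 1 and 5 adjusted over the list alone, and vkg, a collagen gene, was at -1.74 ± 0.22 (camera adjusted p = 0.524, downward, with a median of -0.56 and a mean of 0.12). Corrected for length 2 rose and 0 fell, and vkg was no longer called (-0.26 ± 0.23, edgeR adjusted p = 0.380). Of 14 myoblast markers 5 rose and 5 fell, or 5 and 6 adjusted over the list alone, with Ama at 1.36 ± 0.09 and mbc at -1.90 ± 0.13 (camera adjusted p = 0.695); 5 rose and 1 fell with the correction, where Ama was at 1.06 ± 0.10 and mbc at -0.30 ± 0.09. Of 12 tracheal markers 1, pio, rose and 6 fell, the same adjusted over the list alone, with trh at -1.17 ± 0.11 (camera adjusted p = 0.128); 2 rose and 4 fell with the correction, where trh was not called (-0.03 ± 0.14, 0.870). Of 10 neuron and glia markers 1 rose and 6 fell, or 1 and 7 adjusted over the list alone, with loco at -0.96 ± 0.08 (camera adjusted p = 0.118); 1 rose and 2 fell with the correction, where loco was not called (-0.20 ± 0.09, 0.105). Of 9 eye-antennal disc markers 1, ato, rose and 2 fell, so (-3.05 ± 0.86) and eya (-2.86 ± 0.87), the same adjusted over the list alone (camera adjusted p = 0.936, downward, with a median of 0.20 and a mean of -0.31). Without ds38k replicate 4 the values of so and eya were -4.38 and -4.25. The call of eya was lost without WT replicates 1, 2 and 3 (edgeR adjusted p = 0.0555, 0.0529, 0.0513) and without ds38k replicate 1 (0.0551); the counts with the correction were also 1 and 2. Of 13 leg and haltere disc markers 1 rose and 5 fell, or 1 and 4 adjusted over the list alone, with dac at -2.50 ± 0.46 (camera adjusted p = 0.201); 1 rose and 3 fell with the correction, where dac was at -1.26 ± 0.42. Of 7 immune genes 1, TotA, rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.956, upward, with a median of -0.28 and a mean of 0.80). The edgeR adjusted p of TotA, 0.029, was 0.0843, 0.0990 and 0.0780 without WT replicates 1, 2 and 3. In the corrected fit 0 rose, with TotA at 2.72 ± 1.08 against 3.55 ± 1.16 (edgeR adjusted p = 0.0742), and 1, PGRP-SA, fell, a gene with an uncorrected adjusted p of 0.073, and of 0.0499 without WT replicate 3.

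Of 6 sex-biased genes 5 fell and 1 rose, the same adjusted over the list alone, with the dosage compensation RNA roX1 (lncRNA:roX1) at 1018, 1838 and 1779 CPM in WT and 404, 313, 279.8 and 484 CPM in ds38k (camera adjusted p = 0.0657, and 0.0454 with upper-quartile factors). After the correction 4 fell and 0 rose (0.0284, and 0.582 with an estimated correlation). Of 3 marker genes of the genetic background 1, w, rose, the same adjusted over the list alone (camera adjusted p = 0.706). The white gene w, which the w1118 stock is named for, had 0.171, 0.0856 and 0.311 CPM in WT and 1.61, 1.01, 1.69 and 12.0 CPM in ds38k. With the correction 1 rose and 0 fell.

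Called genes were spread over the genome. Within 1 Mb of ds 101 of 140 tested genes were called (72.1%) against 955 of 1470 (65.0%) on the rest of 2L, an odds ratio of 1.40 with a two-sided Fisher's exact p of 0.0941; within 5 Mb the odds ratio was 1.202 (Fisher's exact p = 0.125), and with the length correction it was 1.26 within 1 Mb (Fisher's exact p = 0.214). Leaving out the Y chromosome, with 1 tested gene, which was called, the share of called genes ran from 62.2% on 2R to 69.5% on chromosome 4, where 12 genes were higher and 45 lower (chi-square 11.1 over these arms, p = 0.0485). On the X 464 genes were higher and 579 lower. More genes were higher than lower on 2L (587 and 470), 2R (631 and 548), 3L (639 and 556) and 3R (825 and 628). These counts carry no length correction, and the direction by arm and its cause were not tested.

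Some genes, all picked after their values were seen, were abundant in part of a group and nearly without counts in the rest. In WT p24-2 had 1010, 0 and 0 CPM in replicates 1 to 3, and the overlapping Unc-115b had 256, 0 and 0 CPM; in ds38k p24-2 had 13.5, 0.0794, 1.68 and 178 CPM. CG18853 had 128, 0 and 0 CPM in WT and 117, 119, 104 and 0 CPM in ds38k. The gene spok, which encodes an enzyme of ecdysone synthesis, had 65.3 CPM in ds38k replicate 3 and at most 0.0631 CPM in any other library. Of the digestive protease genes yip7 had 90.1, 0.0397, 383 and 0.0321 CPM in ds38k replicates 1 to 4 and Jon65Aiii had 63.7, 0.357, 328 and 0.0642 CPM, with at most 0.378 CPM for either in WT. Hsp70Aa, a member of a group of near-identical copies whose reads can be shared, had 2262 CPM in ds38k replicate 4 and no counts elsewhere.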
